A study of Mus musculus with 4 samples.

How the data were processed

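RNA was measured in 4 libraries of sorted thymic iNKT cells, 2 from WT and 2 from Mettl3 knockout mice, and groups and replicate numbers were taken from the sample labels. The deposited table holds raw read counts per gene, whole numbers for 53715 versioned Ensembl gene IDs with 1 column per library, and the authors did not pool replicates in it. Per the submitters' processing notes, the tools were FastQC 0.11.5, STAR 2.6.0a, HTSeq 0.6.1 and DESeq2 1.18.1 with genome build mm10; which step each tool served, the annotation release, the strand setting and any filter are not given in the sources used here. Per the labels' protocols the libraries were Smart-seq2, which does not mark strand, so genes that overlap or run antisense to each other share reads and are uncertain, as are near-identical copies. That includes the mitochondrially encoded genes, which have nuclear copies, and paralogous receptor genes such as the Klr and Cd209 families.

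The IDs were matched to the GENCODE M21 annotation of GRCm38: 53620 matched without the version suffix and 51464 with it, 95 had no symbol, and 93 symbols stood on more than 1 ID, of which the ID with the highest total count was used in gene lists. Coordinates are printed only for genes whose ID version matched. No row of the table lacked a gene ID, and no column lacked a sample.

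Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr, libraries were scaled by TMM (factors 0.994, 0.969, 1.01 and 1.02 in the order WT replicates 1 and 2, knockout replicates 1 and 2), and genotypes were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, legacy=FALSE, robust=TRUE), two-sided, on all 4 libraries with no covariate and 2 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. SE is the log2 fold change divided by the square root of the F statistic, and intervals are at 95%. For a gene with no count in either library of a genotype, the fold is given as a lower bound at 3 counts per library, which correspond to 0.107, 0.119, 0.117 and 0.12 CPM. Intervals and floors cover counting and library error only, since reads without molecular identifiers are not independent molecules.

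Gene lists were fixed before the data were examined. They are the m6A methyltransferase complex, m6A readers and erasers, iNKT lineage regulators, markers of stage 0, NKT1, NKT2 and NKT17 cells, T cell receptor signalling, cytokine receptors and JAK-STAT, the SOCS family, p53 targets, apoptosis regulators, cell cycle, interferon-stimulated genes, immediate early and stress genes, the CREB family, glycolysis, oxidative phosphorylation, the endoplasmic reticulum stress response, migration and thymic exit, invariant receptor segments, markers of CD4+CD8+ thymocytes, conventional single-positive T cells, gamma-delta T cells, B cells, myeloid cells, erythroid cells and thymic stroma, sex-linked genes and mitochondrially encoded genes. Each of the 30 lists was tested by limma 3.58.1 camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list differs from the other tested genes. Of the 16 lists called with the preset correlation, 0 were called with an estimated correlation, and fry, which asks whether the genes of a list move one way and compares them with no other genes, called 0, with a lowest adjusted p of 0.0537; its test for change in either direction called 27 of the 30. List medians were the same when the 4 members with no count in 1 genotype (Il17a, Aire, Cdh5 and Col1a1) were set at their bounds.

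Genes named in the text follow a rule that was also fixed before the data were examined. It always takes, among others, Mettl3, Mettl14, Wtap, Creb1, Zbtb16, Tbx21, Gata3, Egr2, Il7r, Socs1, Socs3, Cish, Bcl2 and Cdkn1a. It adds the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM in the higher genotype and no overlap, leaving out predicted genes, clones, small RNAs, receptor and immunoglobulin segments, pseudogenes and sex-linked genes. From each list it takes up to 4 members with the smallest p, and every member of lists of 8 or fewer. Cd79a, Il17a, Cst3, Ctss, C1qa, Tyrobp, Gzmb and Gm43305 were named outside the rule, after their values were seen. Where the text says that a gene did not pass without a library, the adjusted p is that of the same edgeR test on the other 3, in which the lone library of a genotype is assumed to vary like the others.

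The libraries of a genotype were compared before averaging. They differed beyond counting noise, with a chi-square per degree of freedom of 45.6 in WT and 28.7 in the knockout, and were used as separate replicates. Pearson's r of log2 CPM across genes was 0.933 within WT, 0.931 within the knockout and 0.902 to 0.907 between genotypes, and the first principal component, with 48.1% of the variance, separated the genotypes. The 10 most counted genes held 3.73% to 3.87% of counts, mitochondrially encoded genes 0.805% to 0.928% and ribosomal protein genes 1.21% to 1.45%. The labels name no sequencing batch or date.

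Scripts were tested on simulated counts with the means and library sizes of 14185 genes, of which 13450 passed the filter. Changes were planted only in genes with a mean of at least 100 counts. The test recovered 49% of 100 such genes changed 2-fold and 73% of 100 changed 4-fold, with 7 false calls among 129. A planted list of 20 such genes was called (camera adjusted p = 2.49e-44), with 0 of 30 other lists called. It was not called with an estimated correlation (camera adjusted p = 0.127). Genes were simulated independently, so this does not check lists of correlated genes, such as NKT1 markers (estimated correlation 0.662).

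Alternatives were other scalings (median-of-ratios, upper quartile, total count), DESeq2 1.42.0, limma voom, no low-count filter or at least 5 CPM in 2 libraries, robust=FALSE, legacy=TRUE, the replicate number as a block, each library left out, mitochondrial, ribosomal, receptor and haemoglobin genes left out, other thresholds, and for lists an estimated correlation, ranks and fry. Removal of the gene-length trend by loess offsets was added after seeing the data. The offsets were not recentred, and the median log2 fold change of all tested genes moved from 0.0163 to -0.0775. Values from that fit are therefore shifted down in general. Motif sites were counted in the 3′ UTR of the longest protein-coding transcript of each gene in the same annotation, for UTRs of at least 200 nt.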

Results

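Invariant natural killer T (iNKT) cells, T cells whose semi-invariant receptor recognises lipids on CD1d, were profiled from mouse thymus by RNA sequencing. Live cells that bound a CD1d tetramer and carried TCRβ were sorted, and libraries were made by Smart-seq2, a full-length cDNA method that does not mark strand. Wild-type (WT) C57BL/6 mice gave 2 libraries, and mice carrying a floxed Mettl3 gene and Cre recombinase driven by Cd4, here called Mettl3 knockout, gave 2 libraries. METTL3 is the catalytic subunit of the complex that writes the m6A mark on mRNA, and the comparison asks how its loss alters the transcripts of developing iNKT cells. The counts over genes totalled 28316016 and 25931610 in WT replicates 1 and 2, and 25402792 and 24374587 in Mettl3 knockout replicates 1 and 2. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Levels below are CPM (counts scaled to library size) after TMM scaling, with 2 libraries per genotype. Fold changes, standard errors (SE) and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

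The targeted gene, Mettl3 (ENSMUSG00000022160.18; GRCm38 chromosome 14, 52294841 to 52305128, minus strand, protein coding), was at 92.2 and 123.6 CPM in the WT libraries and at 78.1 and 91.4 CPM in the Mettl3 knockout libraries. Its log2 fold change was -0.35 (SE 0.19, 95% interval -0.79 to 0.09; edgeR adjusted p = 0.357), which did not pass the test. Without WT replicate 2 the value was -0.13, and without WT replicate 1 it was -0.56. Every knockout library lay below both WT libraries, at means of 84.7 ± 9.39 against 107.9 ± 22.2 CPM (SD, n = 2). The counts cover the whole gene, and transcript from exons outside the deleted part still counts, so this value does not settle whether the allele was deleted in these cells. The other members of the m6A methyltransferase complex did not pass the test either: of 8 tested genes, 0 rose and 0 fell, while 2 were higher when adjusted over the list alone. Virma, the scaffold of the complex, had a log2 fold change of 0.57 (SE 0.12, edgeR adjusted p = 0.0575), and Rbm15, an RNA-binding subunit, 1.13 (SE 0.27, edgeR adjusted p = 0.0789). Both passed with DESeq2 (adjusted p = 0.000521 and 0.00393) and at 5 CPM or more in 2 libraries (0.0299 and 0.0342), and Virma did with total-count scaling (0.0431). Mettl14, the partner of METTL3, and Wtap had log2 fold changes of -0.23 and -0.09.

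In the Mettl3 knockout 20 of 23 NKT1 markers and 8 of 18 NKT17 markers fell, while genes of stage 0 and NKT2 cells such as Satb1, Hivep3, Ccr7 and Il6ra rose. Camera called both the NKT1 and the NKT17 list with its preset correlation, but neither with an estimated correlation (adjusted p = 0.314 for both). With an estimated correlation, camera also missed a planted list in simulated counts (adjusted p = 0.127). A missing call there, for these and the lists below, therefore does not show that a list is unchanged. Of 14185 genes tested, 154 were higher and 214 lower in the knockout (edgeR adjusted p under 0.05), and 111 and 142 of these differed at least 2-fold. The balance of higher and lower genes depended on the scaling and the test: total-count scaling gave 208 higher and 197 lower, and DESeq2 665 and 676. Removing the trend of counts with gene length, an alternative chosen after seeing the data, gave 120 and 317. That fit also moved the median log2 fold change of all tested genes from 0.0163 to -0.0775, which favours lower calls. All 368 called genes had no overlap between the genotypes, as did 50.3% of the tested genes, where chance gives 33.3%. The count depended on single libraries and on the test: it was 172 without WT replicate 1, 84 without WT replicate 2, 41 without Mettl3 knockout replicate 1 and 45 without Mettl3 knockout replicate 2. DESeq2 called 1341 genes, with 362 of the 368 among them in the same direction, and limma voom called 269, with 264 shared.

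**Figure D1:**
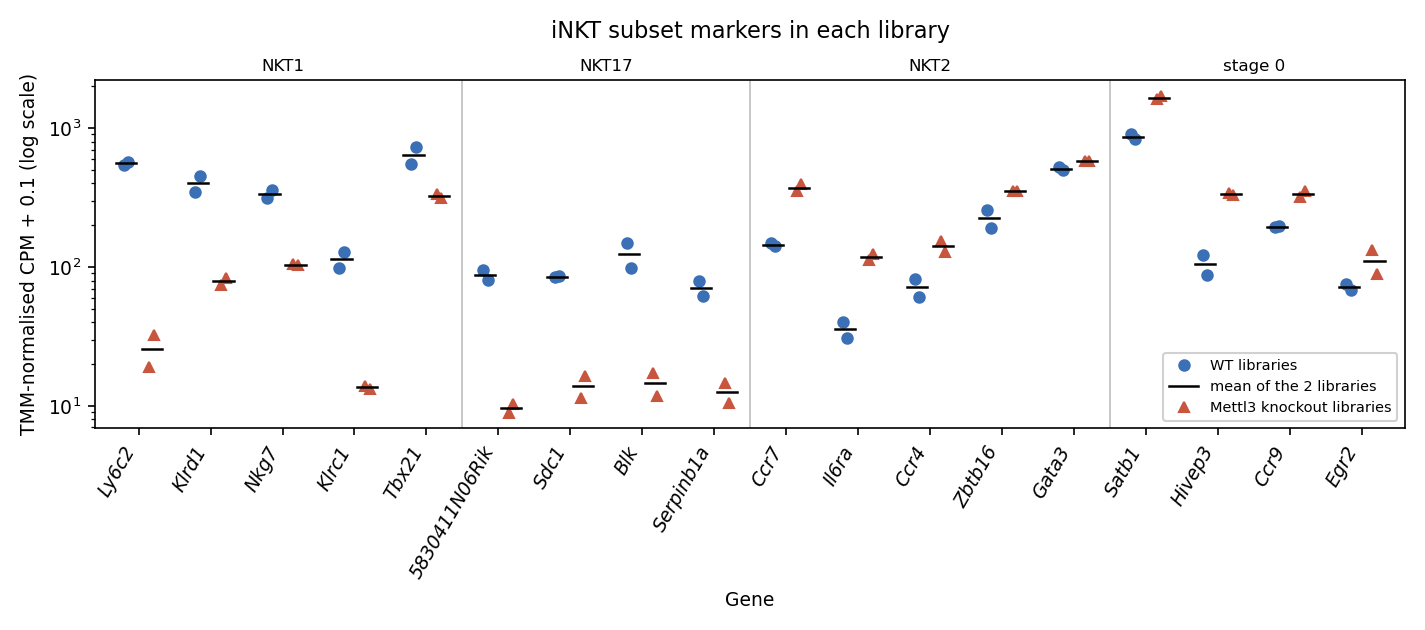
TMM-normalised CPM, with 0.1 added and on a log axis, of 18 iNKT subset markers in each library; circles are WT libraries, triangles Mettl3 knockout libraries and bars the mean of 2 libraries. Both knockout libraries lie below both WT libraries for the NKT1 and NKT17 markers shown, and Ly6c2 falls from a mean of 559.9 to 25.5 CPM.

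NKT1 markers, the genes of the interferon-γ-producing subset, showed the broadest change. Of 23 tested, 20 fell and 0 rose, 22 fell when adjusted over the list alone, and all 23 had a negative log2 fold change, with a median of -1.71. The list differed from other genes by camera (adjusted p = 2.5e-64), and adjusted p = 0.314 with an estimated correlation. Ly6c2 (ENSMUSG00000022584.14; GRCm38 chromosome 15, 75108158 to 75111970), a surface antigen of memory-like lymphocytes, fell by 4.46 on the log2 scale, from 559.9 ± 18.8 to 25.5 ± 9.28 CPM (SD, n = 2; edgeR adjusted p = 0.000799). The natural killer receptor genes Klrc1 and Klrd1, whose products pair as an inhibitory receptor, fell by 3.07 (SE 0.23) and 2.35 (SE 0.17) on the log2 scale (edgeR adjusted p = 0.00217 and 0.00213), and the cytotoxic granule gene Nkg7 fell by 1.69 (SE 0.13; edgeR adjusted p = 0.00213). Tbx21, which encodes T-bet, the transcription factor of NKT1 cells, fell 1.97-fold, from 642.1 ± 126.7 to 326.2 ± 16.4 CPM (edgeR adjusted p = 0.0202). Outside the list, the 10 largest falls of called genes with at least 10 CPM in WT included 3 killer cell lectin-like receptor genes, with Klre1 down 14.6-fold, Klrc2 13.7-fold and Klri2 16.4-fold. They also included the integrin gene Itga1, down 14.7-fold, and Fgl2, a fibrinogen-like immunoregulator, down 13.1-fold. Cdh1, which encodes E-cadherin, fell 18.3-fold (edgeR adjusted p = 0.0431). Ly6c2 and the Klr genes and Nkg7 passed whichever library was left out. Tbx21 did not pass without WT replicate 2 (adjusted p = 0.0529), knockout replicate 1 (0.115) or knockout replicate 2 (0.148), nor did Cdh1 (0.0761, 0.212 and 0.177), whose log2 fold change was -3.18 without WT replicate 2 and -4.82 without WT replicate 1, against -4.19. Fgl2 did not pass without knockout replicate 1 (0.0511), and Itga1 did not without WT replicate 2 (0.129) or knockout replicate 1 (0.115), and its log2 fold change was -6.56 without knockout replicate 2, -2.98 without knockout replicate 1 and -3.24 without WT replicate 2, against -3.88.

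Among called genes with at least 10 CPM in WT, predicted genes aside, the 3 largest falls were of genes near 0 in the knockout. Tgfa, a growth factor gene, was at 13.3 CPM in WT and 0.0389 CPM in the knockout (edgeR adjusted p = 0.0351), Apol7b fell by 5.99 on the log2 scale to 0.221 CPM (adjusted p = 0.011) and Kcnj8, a potassium channel gene, fell by 5.04 from 49.9 CPM (adjusted p = 0.0134). Tgfa passed only without WT replicate 1 (0.0474); it did not without WT replicate 2 (0.109), knockout replicate 1 (0.138) or knockout replicate 2 (0.147). Apol7b passed only without WT replicate 2 (0.0319), and not without WT replicate 1 (0.0506), knockout replicate 1 (0.122) or knockout replicate 2 (0.0976). Kcnj8 did not pass without knockout replicate 1 (0.0673). Without knockout replicate 2, which held the only counts of Apol7b and Kcnj8 in that genotype, they were at least 119.5-fold and 426.3-fold lower against a floor of 3 counts. Without knockout replicate 1 their log2 fold changes were -4.98 and -4.02. Tgfa, then with no knockout count, was at least 110.7-fold lower, and its value was -7.32 without knockout replicate 2, against -8.21.

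NKT17 markers, the genes of the interleukin-17-producing subset, fell as a list, with 8 of 18 tested genes lower and 0 higher, 12 lower and 1 higher when adjusted over the list alone, and a median log2 fold change of -1.70. The camera test gave adjusted p = 7.73e-20, and adjusted p = 0.314 with an estimated correlation. Sdc1, which encodes syndecan-1, fell 6.19-fold, from 85.3 ± 0.406 to 13.8 ± 3.41 CPM (edgeR adjusted p = 0.00342), Blk, a Src-family kinase gene, fell 8.53-fold (adjusted p = 0.00465) and Serpinb1a 5.69-fold (adjusted p = 0.00652). Another member, 5830411N06Rik, fell 9.16-fold (edgeR adjusted p = 0.00213). Of these, Serpinb1a alone depended on a library, with adjusted p = 0.0568 without knockout replicate 2. Il17a itself averaged 1.38 CPM in WT and 0 in the knockout, at least 11.7-fold lower against a floor of 3 counts per library, and did not pass the test (edgeR adjusted p = 0.155).

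NKT2 and stage 0 markers were higher as lists by camera, and so were markers of conventional single-positive T cells (median 0.69) and CD4+CD8+ thymocytes (median 0.48). With an estimated correlation none of the 4 lists was called: adjusted p = 0.392 for NKT2 and CD4+CD8+ thymocyte markers and 0.314 for stage 0 and single-positive markers. Whether the lists differ from each other was not tested. Ccr7 is shared with the single-positive list and Cd4 with the CD4+CD8+ list, and the 10 NKT2 markers on no other cell type list had a median of 0.70. Of 12 NKT2 markers, 3 rose and 0 fell, 8 rose and 1 fell when adjusted over the list alone, and the median log2 fold change was 0.70 (camera adjusted p = 2.82e-07; adjusted p = 0.392 with an estimated correlation). The members that rose encode receptors also found on naive or helper T cells: the chemokine receptor Ccr7 rose 2.57-fold, from 145.1 ± 5.91 to 373.3 ± 29.2 CPM (edgeR adjusted p = 0.00342), the interleukin-6 receptor Il6ra 3.31-fold (adjusted p = 0.0068) and Ccr4 1.96-fold (adjusted p = 0.0458). Zbtb16, which encodes PLZF, the master regulator of iNKT cells, was at 223.9 ± 44.7 CPM in WT and 351.5 ± 1.61 CPM in the knockout, a log2 fold change of 0.65 (SE 0.15; edgeR adjusted p = 0.0659) that did not pass the test. It was 0.86 and passed without WT replicate 1 (adjusted p = 0.0394), and Zbtb16 also passed with DESeq2 (0.000913) and at 5 CPM or more in 2 libraries (0.0278). Gata3 was at 511.0 and 577.3 CPM (edgeR adjusted p = 0.326). Of 12 stage 0 markers, genes of the earliest iNKT precursors, 4 rose and 0 fell, 7 rose and 1 fell when adjusted over the list alone, and the median was 0.63 (camera adjusted p = 3.1e-07; adjusted p = 0.314 with an estimated correlation). Satb1, a chromatin organiser of thymocytes, rose 1.91-fold, from 866.7 ± 50.5 to 1659 ± 72.1 CPM (edgeR adjusted p = 0.00395). Hivep3, a zinc finger gene, rose 3.16-fold (adjusted p = 0.00558), the thymic homing receptor Ccr9 1.72-fold (adjusted p = 0.0179) and Lef1 1.68-fold (adjusted p = 0.0112). Egr2, an inducer of PLZF, was at 71.9 and 111.0 CPM (edgeR adjusted p = 0.158). Ccr7 and Satb1 passed whichever library was left out. Without knockout replicate 1 or 2, Il6ra (adjusted p = 0.0538 and 0.0635) and Lef1 (0.115 and 0.0978) did not pass, nor did Lef1 without WT replicate 2 (0.0519) or Hivep3 without knockout replicate 1 (0.0519). Ccr9 and Ccr4 did not pass with any library left out, with adjusted p of 0.0725 and 0.0708 without WT replicate 1, 0.0812 and 0.168 without WT replicate 2, 0.0982 and 0.234 without knockout replicate 1, and 0.156 and 0.151 without knockout replicate 2.

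Among 30 iNKT lineage regulators, 4 rose and 1 fell, 10 rose and 3 fell when adjusted over the list alone, and the median was 0.23 (camera adjusted p = 0.0103; adjusted p = 0.392 with an estimated correlation). Id3, an inhibitor of E proteins, rose 2.10-fold (edgeR adjusted p = 0.00965) and Egr1, an early response factor downstream of the T cell receptor, 1.82-fold (adjusted p = 0.0119), while Tbx21 was the member that fell. Id3 passed only without WT replicate 1 and had adjusted p = 0.0554 without WT replicate 2, 0.0846 without knockout replicate 1 and 0.0516 without knockout replicate 2. Egr1 did not pass with any library left out (0.0582 and 0.0703 without WT replicates 1 and 2, 0.113 and 0.0605 without knockout replicates 1 and 2). Camera no longer called this list without WT replicate 2 (median 0.07, adjusted p = 0.0899) or without Mettl3 knockout replicate 1 (median 0.23, adjusted p = 0.128), nor with the gene-length trend removed (median 0.14, adjusted p = 0.0508). Its median was 0.35 without WT replicate 1. Creb1, an activity-dependent transcription factor, was at 102.1 and 75.1 CPM (edgeR adjusted p = 0.158), and 0 of 11 genes of the CREB family and its coactivators passed over all genes or when adjusted over the list alone.

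Transcripts of other cell types also differed between the genotypes. B cell markers were higher in the knockout, with 3 of 12 tested genes higher over all genes and when adjusted over the list alone, 0 lower, and a median log2 fold change of 1.49 (camera adjusted p = 2.04e-08; adjusted p = 0.392 with an estimated correlation). The 3 that rose were H2-Ab1, H2-Aa and Cd74, which encode the MHC class II chains and their invariant chain and are shared by all antigen-presenting cells: H2-Ab1 rose 14.9-fold, from 42.2 ± 18.3 to 623.8 ± 46.0 CPM (edgeR adjusted p = 0.00213). Without WT replicate 2 the B cell median was 2.39. The B cell receptor gene Cd79a was at 2.76 and 6.43 CPM (edgeR adjusted p = 0.254). Of 15 myeloid markers, 2 rose and 0 fell, 3 rose when adjusted over the list alone, and the median was 0.79 (camera adjusted p = 0.00631; adjusted p = 0.361 with an estimated correlation). Lyz2, which encodes lysozyme, rose 9.27-fold, from 38.6 ± 12.7 to 355.1 ± 43.1 CPM, and Csf1r, the receptor for macrophage colony-stimulating factor, rose 49.8-fold from 0.427 CPM (edgeR adjusted p = 0.00213 and 0.0137). The myeloid list lost its call without WT replicate 1 (median 0.77, adjusted p = 0.112), Mettl3 knockout replicate 1 (median 0.27, 0.119) or Mettl3 knockout replicate 2 (median 0.52, 0.129). It was also not called with limma voom (0.0976) or by camera on ranks (0.122), and at 5 CPM or more in 2 libraries its median was 0.27. The lectin receptor genes Cd209a, Cd209d and Cd209e and Mgl2, expressed by dendritic cells and macrophages, were among the 10 largest rises of called genes with at least 10 CPM in the knockout and rose 42.6-fold, 33.8-fold, 27.0-fold and 19.6-fold, and the inhibitory Fc receptor gene Fcgr2b rose 20.3-fold. Il13ra1 was not counted in either WT library and averaged 11.7 CPM in the knockout, at least 103.4-fold higher than a floor of 3 counts per library (edgeR adjusted p = 0.039). Ccl9, a chemokine gene, rose 26.6-fold, Ptpro 20.9-fold and Fstl1 18.8-fold.

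H2-Ab1, Lyz2, Cd209d, Cd209e and Fcgr2b passed whichever library was left out. WT replicate 2 held more MHC class II transcript than WT replicate 1, with 59.9 and 21.2 CPM of H2-Aa. Without WT replicate 2 the log2 fold changes of H2-Aa, Cd74, Cd209d, Cd209e and Mgl2 were 4.70, 4.42, 8.19, 6.58 and 5.82, against 3.78, 3.67, 5.08, 4.75 and 4.29 with all libraries. Those of Ccl9 and Ptpro were then 5.80 and 5.59, against 4.73 and 4.38. Without WT replicate 1 the values were 3.19 for H2-Aa, 4.33 for Cd209a (against 5.41), 4.08 for Cd209d, 3.89 for Cd209e, 3.49 for Mgl2, 4.06 for Ccl9 and 3.67 for Ptpro. Csf1r was at 4.72 without WT replicate 2 (against 5.64), and Ptpro at 3.70 without knockout replicate 1. Without WT replicate 2 Cd209a had no WT count and was at least 316.9-fold higher against a floor of 3 counts, as was Csf1r, at least 189.9-fold, without WT replicate 1. Without knockout replicate 1, edgeR adjusted p was 0.114 for H2-Aa, 0.0673 for Cd74 and 0.0764 for Csf1r. Without knockout replicate 2 it was 0.122 for H2-Aa, 0.0635 for Cd74, 0.0543 for Cd209a and 0.0635 for Mgl2. Without WT replicate 1 it was 0.0917 for Csf1r and 0.0721 for Mgl2, and without WT replicate 2 it was 0.129 for Csf1r and 0.0574 for Mgl2. Il13ra1 and Fstl1 did not pass with any library left out (up to 0.145 and 0.093). Ccl9 passed only without knockout replicate 1 and Ptpro only without knockout replicate 2 (up to 0.143 and 0.172 otherwise).

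**Figure D2:**
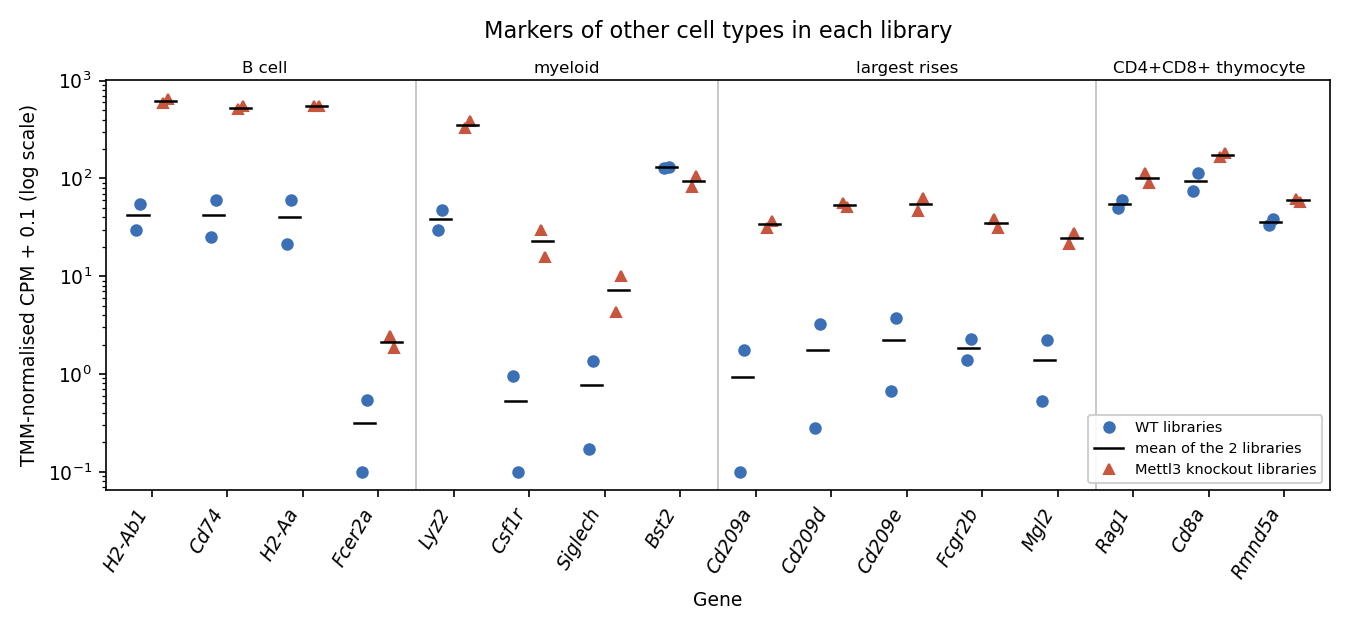
TMM-normalised CPM, with 0.1 added and on a log axis, of 16 markers of other cell types and of the largest rises in each library; circles are WT libraries, triangles Mettl3 knockout libraries and bars the mean of 2 libraries. H2-Ab1, Cd74, H2-Aa and Lyz2 lie at means of 355.1 to 623.8 CPM in the knockout and 38.6 to 42.4 CPM in WT, while Bst2 does not follow them.

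Markers of conventional thymocytes were higher as lists. Of 10 conventional single-positive T cell markers, 3 rose and 0 fell, 5 rose when adjusted over the list alone, and the median was 0.69 (camera adjusted p = 9.46e-08; adjusted p = 0.314 with an estimated correlation). Igfbp4 rose 2.04-fold (edgeR adjusted p = 0.00558) and S1pr1, the receptor that drives thymic exit, 1.78-fold (adjusted p = 0.0286). Igfbp4 did not pass without knockout replicate 1 (0.0527) or knockout replicate 2 (0.0676), and S1pr1 did not pass with any library left out (0.0963 and 0.119 without WT replicates 1 and 2, 0.147 and 0.199 without knockout replicates 1 and 2). Of 15 markers of CD4+CD8+ thymocytes, 0 passed over all genes and 6 were higher when adjusted over the list alone, with a median of 0.48 (camera adjusted p = 0.00121; adjusted p = 0.392 with an estimated correlation). Rag1, a recombinase gene of immature thymocytes, was at 54.6 and 102.2 CPM (edgeR adjusted p = 0.0556) and Cd8a at 94.4 and 173.8 CPM (adjusted p = 0.0734). Both passed with DESeq2 (0.000913 and 0.00228) and at 5 CPM or more in 2 libraries (0.0237 and 0.0302), and Rag1 did with total-count scaling (0.0431). Erythroid markers (4 tested, median 1.66, camera adjusted p = 0.18), gamma-delta T cell markers (7 tested, median -0.24, adjusted p = 0.401) and thymic stroma markers (8 tested, median -0.05, adjusted p = 0.837) were not called. Over all genes 0 of these passed, and when adjusted over the list alone 3 stroma markers were higher and 1 lower, with 0 in the other 2 lists.

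Cytokine signalling genes changed in both directions. Of 22 genes of cytokine receptors and the JAK-STAT pathway, 2 rose and 3 fell, 3 rose and 9 fell when adjusted over the list alone, and the median was -0.33 (camera adjusted p = 0.00121; adjusted p = 0.478 with an estimated correlation). Stat4, which transmits interleukin-12 signals, fell 4.56-fold (edgeR adjusted p = 0.0168), the interferon-γ receptor chain Ifngr1 3.44-fold (adjusted p = 0.00746) and the interleukin-18 receptor chain Il18rap 2.18-fold (adjusted p = 0.00558), while Ifngr2, the other interferon-γ receptor chain, rose 2.69-fold (adjusted p = 0.0275). Without knockout replicate 1 or 2 these did not pass: Stat4 (0.114 and 0.0755), Ifngr1 (0.0751 and 0.0828), Il18rap (0.0673 and 0.0718) and Ifngr2 (0.169 and 0.122). Without WT replicate 2, Stat4 (0.0703) and Ifngr2 (0.102) did not pass, nor did Ifngr2 without WT replicate 1 (0.117). Il7r had a log2 fold change of -0.34 (edgeR adjusted p = 0.0692) and passed with DESeq2 (0.00219), at 5 CPM or more in 2 libraries (0.0384) and with the gene-length trend removed (0.0472). In the SOCS family of feedback inhibitors, 1 of 8 genes fell, over all genes and when adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.0416; adjusted p = 0.434 with an estimated correlation). That gene was Socs3, which fell 3.77-fold, from 65.6 ± 8.01 to 17.5 ± 3.33 CPM (edgeR adjusted p = 0.0101); Socs1 and Cish had log2 fold changes of -0.21 and -0.83 (adjusted p = 0.527 and 0.202). The SOCS list was not called without WT replicate 2 (median -0.08, adjusted p = 0.421) or Mettl3 knockout replicate 1 (median -0.23, 0.219), and its median was -0.39 without WT replicate 1. Nor was it called with DESeq2 (0.0727), limma voom (0.0885), at 5 CPM or more in 2 libraries (0.0809) or by camera on ranks (0.122). Socs3 passed only without WT replicate 2, with 0.0593 without WT replicate 1, 0.0878 without knockout replicate 1 and 0.0607 without knockout replicate 2.

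Interferon-stimulated genes fell as a list, with 5 of 31 tested genes lower and 0 higher, 7 lower when adjusted over the list alone, and a median of -0.31 (camera adjusted p = 1.24e-05; adjusted p = 0.314 with an estimated correlation). The median was -0.20 without Mettl3 knockout replicate 1 and -0.19 at 5 CPM or more in 2 libraries. Rsad2, an antiviral enzyme gene, fell 4.07-fold, Ifit3 2.67-fold and the RNA sensor gene Ddx58 1.87-fold (edgeR adjusted p = 0.0162, 0.00755 and 0.0145). Without knockout replicate 1 or 2, Rsad2 (0.115 and 0.062), Ifit3 (0.0632 and 0.0828) and Ddx58 (0.113 and 0.147) did not pass, nor did Rsad2 without WT replicate 1 (0.0614) or Rsad2 and Ddx58 without WT replicate 2 (0.101 and 0.0795). Of 28 oxidative phosphorylation genes, 0 passed over all genes or when adjusted over the list alone, by edgeR, but 26 had a negative log2 fold change, with a median of -0.29 (camera adjusted p = 0.00154; adjusted p = 0.487 with an estimated correlation). Sdha, a complex II subunit gene, was at 648.7 and 497.9 CPM (edgeR adjusted p = 0.0692) and passed with DESeq2 (0.00139), at 5 CPM or more in 2 libraries (0.0388) and with the gene-length trend removed (0.0431). Of 30 cell cycle genes, 1 rose, over all genes and when adjusted over the list alone, and the median was 0.28 (camera adjusted p = 0.00085; adjusted p = 0.331 with an estimated correlation); that gene was Mki67, a proliferation marker, which rose 1.81-fold (edgeR adjusted p = 0.0464). The cell cycle median was 0.18 with the gene-length trend removed. Mki67 did not pass with any library left out (0.115 and 0.183 without WT replicates 1 and 2, 0.13 and 0.272 without knockout replicates 1 and 2).

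p53 target genes were mixed. Of 25 tested, 2 rose and 1 fell, 5 rose and 2 fell when adjusted over the list alone, and the median was 0.35 (camera adjusted p = 0.0416; adjusted p = 0.478 with an estimated correlation). Phlda3, an AKT inhibitor gene, rose 2.30-fold and the stress gene Sesn2 2.38-fold, while Sesn1 fell 1.59-fold (edgeR adjusted p = 0.0134, 0.041 and 0.0185). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 0.29 CPM in WT and 4.01 CPM in the knockout (edgeR adjusted p = 0.0635; DESeq2 adjusted p = 0.0108). Bcl2 was at 177.1 and 183.4 CPM (edgeR adjusted p = 0.936), and of 25 apoptosis regulators 1 fell, over all genes and when adjusted over the list alone: Fasl, the death receptor ligand, fell 3.76-fold (adjusted p = 0.0124; camera adjusted p = 0.309 for the list). The p53 list was not called without WT replicate 1 (median 0.21, adjusted p = 0.368), Mettl3 knockout replicate 1 (0.118) or Mettl3 knockout replicate 2 (0.0726). With all libraries it was not called with DESeq2 (0.0727), limma voom (0.0711), 5 CPM or more in 2 libraries (0.078), the gene-length trend removed (0.062) or camera on ranks (0.0957). Phlda3, Sesn2 and Sesn1 did not pass with any library left out: without WT replicate 1 adjusted p was 0.0631, 0.127 and 0.0513, without WT replicate 2 it was 0.0812, 0.168 and 0.076, without knockout replicate 1 it was 0.106, 0.15 and 0.131, and without knockout replicate 2 it was 0.122, 0.232 and 0.159. Fasl did not pass without knockout replicate 1 (0.0764) or 2 (0.1).

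Readers of m6A rose in part. Of 11 m6A readers and erasers tested, 3 rose and 0 fell, over all genes and when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0276; adjusted p = 0.392 with an estimated correlation). Ythdf2, a cytoplasmic reader linked to mRNA decay, rose 1.67-fold, from 335.6 ± 21.6 to 561.2 ± 18.8 CPM (edgeR adjusted p = 0.0137), the nuclear reader Ythdc1 from 128.0 to 255.4 CPM (adjusted p = 0.04) and Hnrnpa2b1 1.29-fold (adjusted p = 0.039). Camera did not call this list without WT replicate 1 (median 0.33, adjusted p = 0.213) or Mettl3 knockout replicate 1 (median 0.06, 0.183), with the gene-length trend removed (median 0.02, 0.062) or on ranks (0.122). Its median was 0.35 without Mettl3 knockout replicate 2 and 0.27 at 5 CPM or more in 2 libraries. Ythdf2 passed only without WT replicate 1 (0.0599 without WT replicate 2, 0.131 and 0.112 without knockout replicates 1 and 2). Ythdc1 and Hnrnpa2b1 did not pass with any library left out: adjusted p was 0.15 and 0.0645 without WT replicate 1, 0.107 and 0.0554 without WT replicate 2, 0.208 and 0.21 without knockout replicate 1, and 0.0863 and 0.248 without knockout replicate 2.

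**Figure D3:**
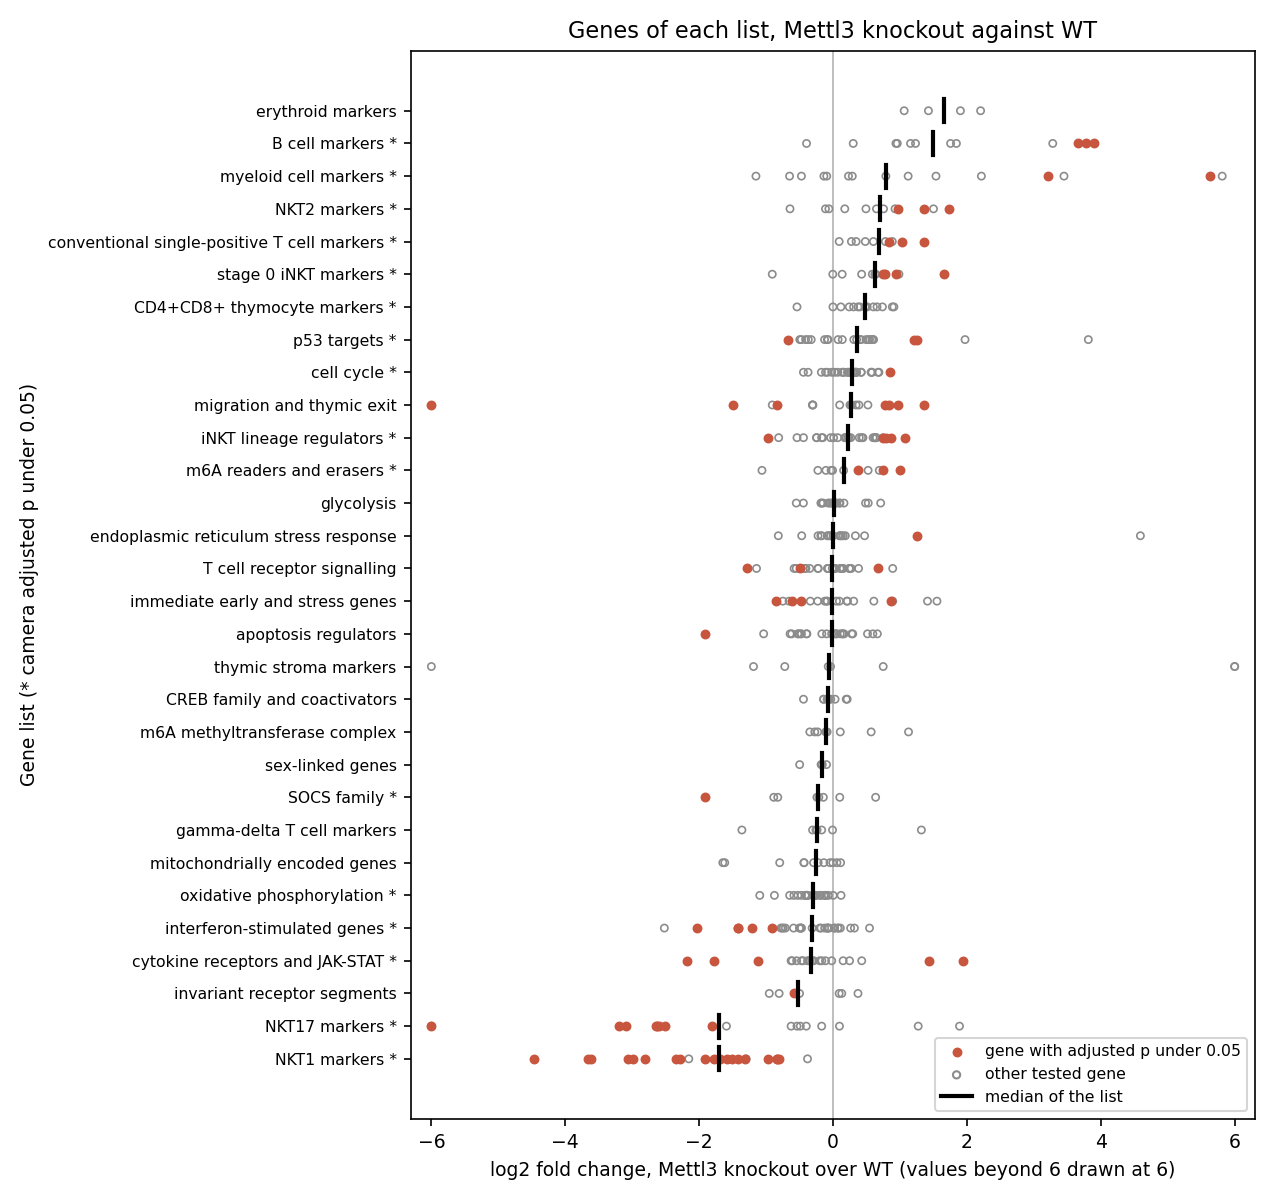
Log2 fold change of every tested gene of 30 lists, Mettl3 knockout over WT; filled points are genes with edgeR adjusted p under 0.05, open points other tested genes, black bars list medians, and 6 values more than 6 from 0 are drawn at the axis limit. The NKT1 and NKT17 medians lie at -1.71 and -1.70, and the B cell median at 1.49.

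Other lists were not called by camera. Of 27 T cell receptor signalling genes, 1 rose and 2 fell, 3 rose and 8 fell when adjusted over the list alone, and the median was -0.01 (camera adjusted p = 0.241). With the gene-length trend removed this list was called lower (median -0.11, camera adjusted p = 0.0442), in a fit where the median of all tested genes was -0.0775. Cd5, a negative regulator whose level follows receptor signal strength, rose 1.60-fold, while Malt1, a protease gene of NF-κB activation, fell 2.45-fold and the phosphatase gene Ptpn6 1.40-fold (edgeR adjusted p = 0.0275, 0.024 and 0.0464). Trac, the receptor α constant gene, fell by 0.58 on the log2 scale (SE 0.07, edgeR adjusted p = 0.0124). It was the 1 change among 8 tested genes of the invariant receptor list, over all genes and when adjusted over the list alone (camera adjusted p = 0.461). That list also holds constant genes and the gene for CD1d, which are not invariant segments. Traj18, the invariant joining segment, was at 3.4 CPM in WT and 2.0 CPM in the knockout (edgeR adjusted p = 0.513). Counts of the short, similar variable segments are uncertain. In the migration list, 4 of 18 genes rose and 3 fell, and 4 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.849). The 4 that rose were Ccr7, Ccr9, S1pr1 and Ccr4, each also on a marker list above. Itgae, the integrin chain that binds E-cadherin, fell 2.80-fold and Cxcr3, also an NKT1 marker, 1.79-fold (edgeR adjusted p = 0.00558 and 0.0173). Of 20 immediate early and stress genes, 1 rose and 3 fell, 3 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.761). Egr1, also a lineage regulator, was the 1 that rose, while Dusp1 fell 1.80-fold and Junb 1.53-fold (edgeR adjusted p = 0.0279 and 0.0475). The endoplasmic reticulum stress list (19 tested, 1 higher, 4 when adjusted over the list alone; adjusted p = 0.351), glycolysis (19 tested, 0 over all genes or the list alone; 0.91), the CREB list (0.581), the m6A methyltransferase complex (0.604), the sex-linked genes (4 tested, 0 over all genes, 1 lower over the list alone; 0.241) and the mitochondrially encoded genes (12 tested, 0 over all genes, 1 lower over the list alone; 0.18) were also not called by camera, though the endoplasmic reticulum stress list was without WT replicate 2 (0.0278) and the mitochondrial list without Mettl3 knockout replicate 2 (0.0484). Without knockout replicate 1 or 2, edgeR adjusted p rose above 0.05 for Cd5 (0.173 and 0.147), Malt1 (0.144 and 0.147), Ptpn6 (0.244 and 0.22), Trac (0.115 and 0.122), Cxcr3 (0.104 and 0.151), Dusp1 (0.141 and 0.0531) and Junb (0.224 and 0.231). Without WT replicate 2 it did for Malt1 (0.102), Ptpn6 (0.118), Cxcr3 (0.0883) and Dusp1 (0.118), without WT replicate 1 for Cd5 (0.0618), Dusp1 (0.101) and Junb (0.08), and for Itgae without knockout replicate 2 (0.0513).

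Median, mean and test differed in sign for 5 lists that were not called: the m6A methyltransferase complex (median -0.10, mean 0.10, test up), the immediate early genes (median -0.02, mean 0.10, test down), glycolysis (median 0.01, mean 0.03, test down), migration (median 0.26, mean -0.37, test up) and thymic stroma (median -0.05, mean 0.93, test up).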

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

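Removal of the gene-length trend was chosen after seeing the data; the other settings were planned. The 368 called genes became 1341 with DESeq2, 727 at 5 CPM or more in 2 libraries (fewer genes tested), 180 with legacy=TRUE and 81 at adjusted p under 0.01, and 41 to 172 when 1 library was left out (fewer samples), with 41 without Mettl3 knockout replicate 1 and 172 without WT replicate 1. The cause was not tested for DESeq2 and legacy=TRUE. Counts in the other settings, apart from the replicate block, ran from 248 to 437, and in no setting did a called gene reverse. Of 69 called genes covered by the naming rule, 17 were called in all 4 fits without a library (Ly6c2, H2-Ab1, Lyz2, Cd209d, Cd209e, Fcgr2b, Klrc1, Klrc2, Klrd1, Klre1, Klri2, Nkg7, 5830411N06Rik, Sdc1, Blk, Ccr7 and Satb1) and 16 in none. Of the 75 that were not called, 27 were called with DESeq2, 14 at 5 CPM or more in 2 libraries, 6 with the gene-length trend removed, 5 with total-count scaling, 2 without WT replicate 1 and 1 with mitochondrial, ribosomal, receptor and haemoglobin genes left out. The log2 fold change of Mettl3 ran from -0.56 without WT replicate 1 to -0.13 without WT replicate 2 and was not called in any setting.

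The labels number the replicates alike in both genotypes. The difference between replicates 1 and 2 in WT correlated across genes at -0.0125 with that in the knockout. This gives no sign of a shared effect, but it cannot show whether same-numbered libraries shared a day or batch, which the labels do not say. With the replicate block, 33 genes and 15 lists (not SOCS, camera adjusted p = 0.0592) were called, with 1 residual degree of freedom left.

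Of 16 called lists, 0 were called with an estimated correlation or by fry, and 11 to 16 in the other settings; the list test was not run for legacy=TRUE, which camera does not use. Outside the estimated correlation and fry, 11 lists were called in every setting; SOCS, p53, myeloid, m6A reader and lineage regulator lists were not. Reversals, where the gene's fold change or the list's test direction changed, touched 12 gene results and 14 list results, and none of these genes or lists was called by the main test. With the gene-length trend removed, Bcl2 was at -0.0378, Socs6 at -0.014 and the migration list at a median of 0.15. The median of all tested genes was -0.0775 in that fit, against 0.0163 in the main fit. Medians in other reversals were 0.0635 for glycolysis with total-count scaling and 0.0165 at 5 CPM or more, -0.71 for thymic stroma at 5 CPM or more and -0.40 with no filter, and -0.10 for the m6A methyltransferase complex with camera on ranks. Without 1 library, log2 fold changes ran from -0.31 to 0.0034 for Atf1, -0.24 to 0.39 for Bcl2, -0.41 to 0.0118 for Eif2s3y, -0.43 to 0.02 for Socs1, -0.0271 to 1.09 for Socs7, -1.52 to 0.13 for Trbv29, -0.36 to 0.14 for Uty and -0.21 to 0.0175 for Wtap. List medians ran from -0.11 to 0.10 for endoplasmic reticulum stress, -0.0389 to 0.0106 for glycolysis, -0.13 to 0.0462 for immediate early genes, -0.17 to -0.0399 for the m6A methyltransferase complex, -0.0544 to 0.28 for migration and -0.43 to 0.64 for thymic stroma. The cause was not tested. Depth limits genes near 0.107 to 0.12 CPM, where 3 counts lie.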

Other observations

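The tests of dilution, of the chromosome 6 haplotype and of gene length for the NKT1 pattern, the test of a lower share of iNKT cells, and the oxidative phosphorylation median with the length trend removed were chosen only after the result, or part of it, was seen.

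The fall of NKT1 markers was weighed against 3 technical explanations. Dilution by cells that lack NKT2 marker transcripts would lower NKT2 markers too. The 10 NKT2 markers held by no other cell type list had a lower quartile of -0.0024 and a median of 0.70, above the NKT1 upper quartile of -1.31. This does not cover dilution by T cells that carry such transcripts, since members such as Ccr4 and Il6ra are also found on naive or helper T cells. A strain haplotype at the natural killer gene complex on chromosome 6 would spare at least the 16 NKT1 markers on other chromosomes. However, 13 of those fell, and the median of the 16 was -1.70, which argues against it. The other 7 lie on chromosome 6, though not all of them need lie in the complex. A trend with gene length is also argued against, since the NKT1 median stayed at -1.70 once that trend was removed; the NKT17 median was then -1.78, and NKT17 markers were not weighed otherwise. Whether other thymocytes are a source of the higher NKT2 and stage 0 markers was not tested, and other thymocyte markers were higher too. What also stays open, and was not tested, is the genotype itself, which may act through fewer NKT1 cells in the sort or through less transcript per cell.

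MHC class II and lectin transcripts were higher in both knockout libraries, though a CD1d tetramer and TCRβ gate would remove antigen-presenting cells. A panel of 46 other dendritic cell and macrophage genes was written before its values were seen; 39 were tested, 8 of them at 10 CPM or more in WT iNKT libraries, and its median log2 fold change was 1.32, with 30 of 39 higher, 7 called higher and 1 called lower, against -0.23 to 0.38 for the middle 95% of expression-matched lists. The 8 genes had a median of -0.14 and the others 1.75. RNA from antigen-presenting cells in the knockout sorts would give such a rise. The panel's rise argues against MHC class II genes switched on in iNKT cells alone, since 0% of 10000 expression-matched lists reached that median. The draws take genes independently, while genes of the same cell type may move together, so this share may be too small. Against a simple source, genes usually abundant in such cells were not called higher: Cst3 was at 7.14 and 4.53 CPM in WT and knockout, C1qa at 7.76 and 7.05, Ctss at 65.7 and 77.2 and the B cell gene Cd79a at 2.76 and 6.43, beside 623.8 CPM of H2-Ab1 in the knockout, and Tyrobp had at most 14 counts in any library. Their low levels beside H2-Ab1 are weak evidence, since Cst3, C1qa, Ctss, Cd79a and Tyrobp are short and may be undercounted. They have 667 to 1457 exonic bases, against a median of 3892 for tested genes, though Lyz2, with 1316, was at 355.1 CPM in the knockout. Undercounting that is alike in both genotypes would not account for the lack of a called rise. Whether it was alike was not tested. Which cells the transcripts could come from is therefore open.

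A lower share of iNKT cells, which would raise the markers of every other type alike, may also have a part. The panel's quartiles, 0.15 to 2.30, overlap those of CD4+CD8+ thymocyte markers, 0.27 to 0.63, as that explanation needs. Medians were also positive for B cell (1.49), myeloid (0.79), erythroid (1.66) and single-positive T cell markers (0.69). They were not for gamma-delta T cell (-0.24) and thymic stroma markers (-0.05), so not every list was higher. This is a weak test, since the panel's range is wide; a narrower reading, that the panel's median lie within the thymocyte quartiles, was tried after the values were seen and is not met, at 1.32. The genotype stays open as an untested explanation of this pattern too.

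The lower oxidative phosphorylation list was weighed against gene length, since its genes are short, with a median exonic length of 2276 bases against 3892 for tested genes, and short genes had lower log2 fold changes. Lists matched on length and expression had a median as low as -0.29 in 0.52% of 10000 draws, which argues against the trend alone. The draws take genes independently, while the list's estimated correlation was 0.217, so this share may be too small. With the length trend removed the list's median was -0.37. The median of all tested genes moved from 0.0163 to -0.0775 in that fit, so the lower value adds no support. The rank correlation of log2 fold change with length across genes was 0.0878, against 0.14 between the WT libraries. The genotype stays open as an untested explanation.

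Loss of m6A may raise transcripts rich in its motif, a hypothesis tested on GGACT sites per kb of 3′ UTR in 7963 expressed genes. The rank correlation of site density with log2 fold change across genes, given UTR length, GC content, gene length and expression, was 0.0267, larger than the 0.0134 between the WT libraries and the 0.0072 between the knockout libraries. Genes are not independent replicates, and the size is small: the median log2 fold change was 0.02 for the 798 genes with the densest sites and -0.01 for the 2484 genes with none.

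A strain haplotype carried along with the floxed allele could change genes near Mettl3. Called genes there included Trac, Gzmb and the predicted gene Gm43305. Of the called genes near Mettl3, Gm43305 changed most, from 22.1 CPM in WT to 0.276 CPM in the knockout (edgeR adjusted p = 0.0021). Within 10 Mb of Mettl3, 6 of 198 tested genes were called, against 362 of 13980 elsewhere, an odds ratio of 1.175 (95% interval 0.423 to 2.63; two-sided Fisher's exact p = 0.649), so too few genes lie there to exclude such an effect or to show one.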
